A study of Homo sapiens with 19 samples.

How the data were processed

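Total RNA of HepG2 cells was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols, and 19 arrays in 7 groups were analysed. The deposited values are on the log2 scale and were made by the authors with RMA, per the submitters' processing notes, a method that corrects the background, normalizes quantiles and summarises the probes of a probe set. The RMA version, the probe-set definition version and any array filter are not given in the sources used here. All 19 columns hold the same sorted values (range 3.17 to 13.78, median 4.83), so the arrays were quantile normalized together. A shift of the whole transcriptome between groups would be removed by this step. No read depth exists for arrays, and the number of arrays limits the precision.

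The deposited table holds 25582 probe sets. The platform annotation names 24244 of them, each with 1 gene symbol, and 1338 are unnamed here and are counted but not named. Symbols were matched through gene identifiers to RefSeq records of the assembly GRCh38.p14, used for names only, for 24195 probe sets. Where 2 probe sets shared a symbol (3 symbols) the one with the higher mean over all arrays was kept, which left 25579 genes. No genome build is named with the values and no coordinates were used here.

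Groups and replicate numbers were taken from the sample titles. A linear model with 1 mean per group was fitted to all 19 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), so that all comparisons share 1 pooled estimate of the spread. No filter on dim genes and no detection call was used. The lowest group means of OR5M8, TUBB1, SYT11, ZNF678, RNASE2, ANKRD1, MYOF and CCN1 lay between 4.24 and 5.02, near the array median, so these are not shown to be above background there and their log2 differences are lower bounds. P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, with a threshold of 0.05. YAP, TAZ and combined knockdown are means over their 2 siRNAs or pairs, compared with control and with one another, and genes that passed with each siRNA in the same direction were counted separately. A gene or list that passed with only 1 siRNA or pair is not thereby shown to differ between the 2. The interaction is the change on adding a YAP siRNA to a TAZ siRNA minus the change with the same YAP siRNA alone. Errors printed as SE are limma's moderated standard errors, and SD is the spread over the arrays of a group.

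The comparisons, tests, 27 gene lists, alternatives and the rule for the named genes were set before the data were examined. Named are YAP1, WWTR1, CCN1, CCN2, ANKRD1 and AMOTL2 in every comparison. In the comparisons of YAP, TAZ and combined knockdown with control and of combined with TAZ knockdown, the 8 largest rises and falls among genes that passed with both siRNAs or pairs are named. In the others the 5 largest rises and falls are named, and the planned rule for a list was up to 4 members with the largest change. In the first 4 comparisons these 4 are named for each list that was called, whether or not they passed, and the further members that passed were added to them after the data were seen. Non-coding RNA and immune receptor segment symbols were left out. The lists hold 531 places, of which 490 were matched to a named probe set. They were tested with camera at a preset inter-gene correlation of 0.01 in 7 comparisons, with adjustment over 189 tests, again with the correlation estimated per list, and with fry, whose directional p-value tests whether the list as a whole changes in 1 direction, without comparison with other genes. List tests per siRNA or pair were added after the data were seen, with adjustment over 216 tests against control and on top of a TAZ siRNA, and over 162 tests in the remaining comparisons. Gene tests per YAP siRNA against TAZ knockdown and per pair of the interaction were also added then.

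The fit was tested on simulated data for the 25579 genes, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale. It recovered 71% and 99% of them for YAP knockdown against control, 74% and 96% for TAZ, 68% and 98% for combined knockdown, 83% and 98% for combined against TAZ knockdown, and 45% and 86% for the interaction. Of all calls, 10 of 180, 16 of 186, 6 of 172, 8 of 189 and 5 of 136 were false in these comparisons. The simulated noise was normal, independent between genes and of equal spread on all arrays. In the data the array labelled siTAZ2 replicate 3 varied more (SD of its deviations from the group mean 0.251). These figures therefore do not describe the fit on these arrays, least of all for TAZ.

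Alternatives were an intensity trend in eBayes, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, quantile normalization once more, centring each array on its median, fitting only the groups compared, the replicate number as a block within each deposit, array weights, and leaving out each array in turn. For the gene lists, the block, the array weights and the left-out arrays were added after the data were seen. The function arrayWeights stopped with a warning that its convergence tolerance was not reached. Because the untreated cells that the treatment protocol mentions are not among the 19 arrays, they were not analysed here.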

Results

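HepG2, an established human liver cancer cell line, was transfected with small interfering RNAs (siRNAs), short duplexes that direct the degradation of a matching mRNA. Gene expression was measured on 19 Affymetrix arrays, 1 per RNA sample. The targets were a pair of related transcriptional co-activators of the Hippo pathway: YAP, encoded by YAP1, and TAZ, encoded by WWTR1, each measured by 1 probe set. Each was targeted with 2 independent siRNAs. The groups were a nonsense control siRNA (n = 3), siYAP1 (n = 3) and siYAP2 (n = 3), both against YAP1, siTAZ2 (n = 3) and siTAZ3 (n = 2), both against TAZ, and the combinations siTAZ2_siYAP1 (n = 3) and siTAZ3_siYAP2 (n = 2). RNA was taken 24 h after transfection. Single siRNAs were used at 20 nM and combinations at 40 nM in total. For the control, the labels can be read as 40 nM in 1 place and as 20 nM in another. Values are log2 RMA values of 25579 genes, of which 1338 probe sets have no gene name here, and the number of arrays limits the precision. The control and YAP arrays also belong to an earlier deposit and the TAZ and combined arrays do not. A difference between the deposits therefore cannot be told apart from the siRNA when TAZ or combined arrays are set against control or YAP arrays. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

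Both targets were lowered in the groups that received their siRNA. YAP1 had a mean of 9.84 ± 0.029 (SD, n = 3) in control, 7.11 ± 0.096 (SD, n = 3) with siYAP1 and 7.13 ± 0.12 (SD, n = 3) with siYAP2, so that 15.1% and 15.3% of the control level remained. In the combined groups 20.2% remained with siTAZ2_siYAP1 and 23.4% with siTAZ3_siYAP2. WWTR1 had a mean of 9.55 ± 0.062 (SD, n = 3) in control, and 16.8% of that level remained with siTAZ2, 11.9% with siTAZ3, 19.7% with siTAZ2_siYAP1 and 10.5% with siTAZ3_siYAP2. All 8 of these decreases passed the limma test, with adjusted p between 1.91e-11 and 6.55e-09. The 3 arrays labelled siTAZ2 read 7.13, 7.02 and 6.77 for WWTR1. The array labelled siTAZ2 replicate 3 stood apart from all others: its median correlation with the other arrays was 0.9866, against at least 0.9927 for each other array. Counts without this array are given beside each comparison, and it is named by its label throughout.

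**Figure D1:**
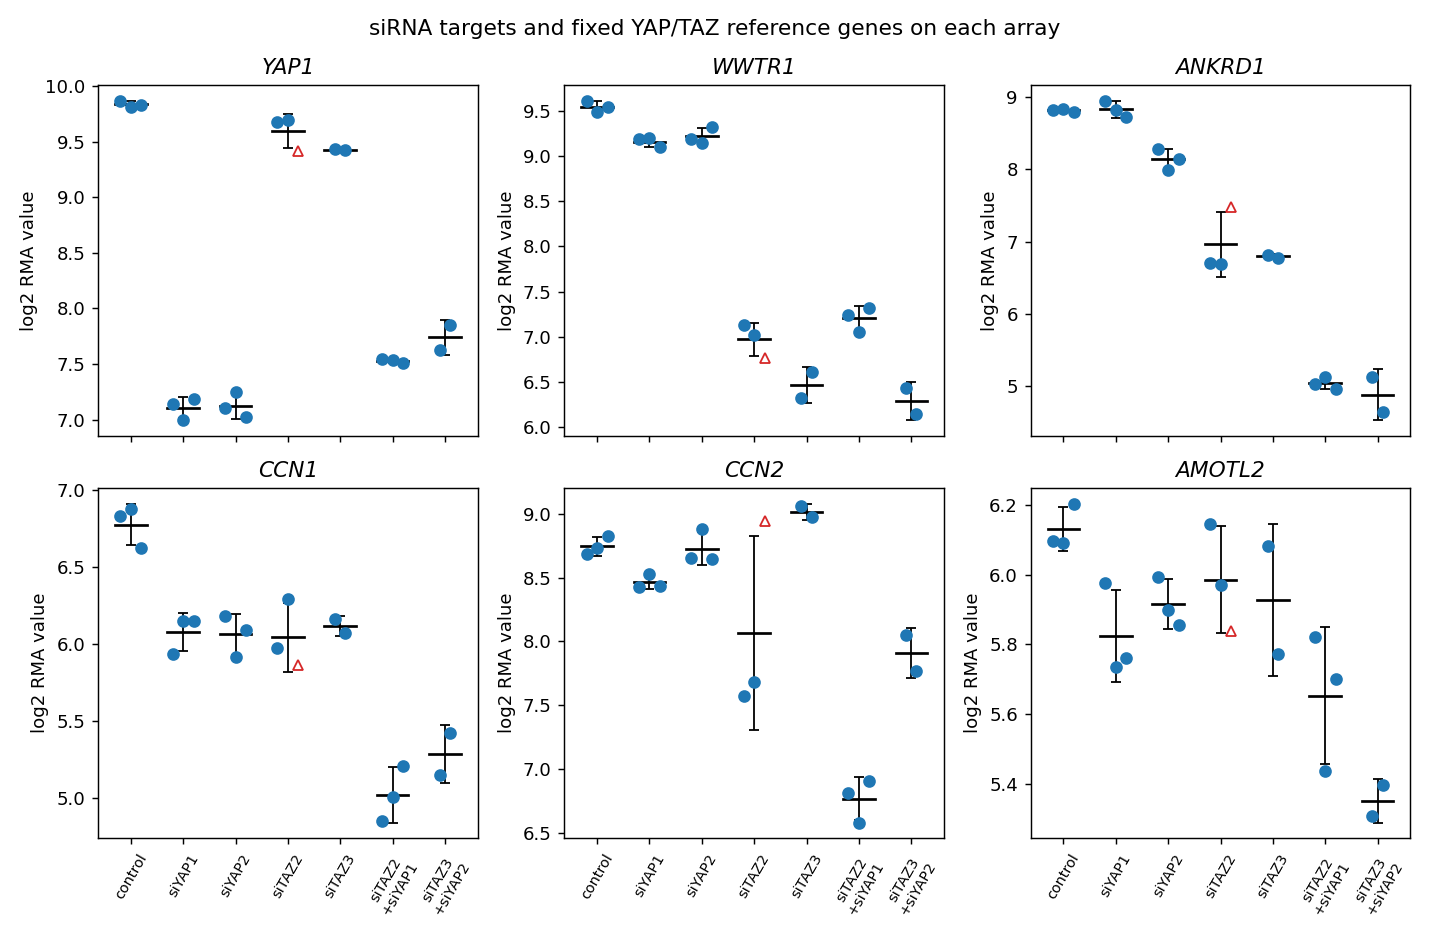
Log2 RMA values (vertical axes) of YAP1, WWTR1, ANKRD1, CCN1, CCN2 and AMOTL2 in the 7 groups (horizontal axis); each point is 1 array, bars are the group mean and SD, and the open triangle is the array labelled siTAZ2 replicate 3. ANKRD1 lay near 8.82 in control and siYAP1, near 7 in both TAZ groups and near 5 in both combined groups.

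YAP knockdown was compared with control to see which genes follow YAP1 in these cells. Besides YAP1, the genes that fell most with both siRNAs included CNIH1, by 0.97 on the log2 scale (SE 0.071), SUZ12, a core subunit of a Polycomb repressive complex, by 0.91 (SE 0.080), the cell adhesion molecule CADM1 by 0.86 (SE 0.080), and AGO2, the Argonaute protein that cleaves siRNA targets, by 0.84 (SE 0.094). RCBTB1 fell by 0.96. The olfactory receptor gene OR5M8 also passed, at 4.95 in control, near the array median of 4.83 and not shown to be above background. CCN1, which encodes a secreted matricellular protein and is a known YAP and TAZ target, fell by 0.71 (SE 0.11, adjusted p = 0.00175). The largest rises were in ZNF678 (1.23, SE 0.16), the lysosomal autophagy gene DRAM1 (1.09), VPS4B, an ATPase of membrane fission (1.05), the peroxisomal acyltransferase CROT (1.01), CFDP1 (0.99), SMIM15 (0.96), the desmosomal cadherin DSC2 (0.87) and DKK4, a secreted Wnt antagonist (0.83). All of these but CROT were higher than control in all 6 siRNA groups. Of those, only DKK4 passed on adding a YAP siRNA to a TAZ siRNA (0.61). For the rest, a shift of the control arrays cannot be told apart from an effect of YAP1 loss. WWTR1 changed by -0.36 (adjusted p = 0.0671), CCN2 by -0.15 (adjusted p = 0.954), ANKRD1 by -0.33 (adjusted p = 0.457) and AMOTL2 by -0.26 (adjusted p = 0.282), none of which passed for the mean of both siRNAs. ANKRD1 fell by 0.68 with siYAP2 (adjusted p = 0.0334) and changed by 0.01 with siYAP1. WWTR1 had adjusted p = 0.0181 without the array labelled siTAZ2 replicate 3.

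After YAP knockdown, of 29 measured genes of the G1/S transition and DNA replication, 3 fell, 0 rose and 26 did not pass, and 8 fell when adjusted over the list alone. The transcription factor E2F1 fell by 0.57, SLBP, the histone mRNA binding protein, by 0.55 and the ribonucleotide reductase subunit RRM2 by 0.35, while PRIM1 (-0.39) and DSCC1 (-0.38) did not pass. E2F1, SLBP and RRM2 passed with siYAP2 (-0.77, -1.01 and -0.61) and not with siYAP1 (-0.37, -0.09 and -0.09; adjusted p = 0.249, 0.877 and 0.752), and 0 genes of the list passed with each siRNA in limma. The median of the list was -0.16 (limma camera, adjusted p = 2.04e-12, and adjusted p = 0.0181 with an estimated correlation). In the chromosomal instability signature, a list of replication and mitosis genes, 2 of 25 fell, CDC45 by 0.48 and MCM2 by 0.41, and 4 fell adjusted over the list alone (adjusted p = 3.38e-08, and adjusted p = 0.0103 with an estimated correlation). CDC45 and MCM2 passed with siYAP2 (-0.81 and -0.45) and not with siYAP1 (-0.15 and -0.36; adjusted p = 0.551 and 0.175), and MELK (-0.23) and RAD51AP1 (-0.23) did not pass. Of 26 mitosis genes KIF23 fell by 0.30, also the only 1 adjusted over the list alone (median -0.09, adjusted p = 0.00475, lost at adjusted p = 0.233 with an estimated correlation). KIF23 passed with siYAP1 and not with siYAP2 (adjusted p = 0.476), and ECT2 (-0.21), PLK1 (-0.18) and CENPA (-0.18) did not pass. Of 20 p53 target genes 4 rose, TIGAR by 0.66, DDB2 by 0.49, SPATA18 by 0.46 and TP53I3 by 0.40, while ZMAT3 (0.44) did not pass, and adjusted over the list alone 6 rose and 1 fell (adjusted p = 0.000284, lost at adjusted p = 0.201 with an estimated correlation). DDB2, SPATA18 and TP53I3 passed with siYAP2 and not with siYAP1 (adjusted p = 0.583, 0.16 and 0.69). The p53 list was called with siYAP2 (adjusted p = 0.000125, lost at adjusted p = 0.166 with an estimated correlation) and not with siYAP1 (adjusted p = 0.0897). Of 25 Hippo pathway and TEAD genes 2 fell, the LIM protein gene AJUBA by 0.35 and MOB1A by 0.34, while WWC1 (-0.43) and TEAD2 (-0.37) did not pass, and 4 fell adjusted over the list alone (adjusted p = 0.00265, lost at adjusted p = 0.153 with an estimated correlation). AJUBA fell almost equally, by 0.37 with siYAP2, where it passed, and by 0.33 with siYAP1, where it did not (limma adjusted p = 0.158). MOB1A passed with siYAP1 and not with siYAP2 (limma adjusted p = 0.081). The Hippo list was called with siYAP2 (camera adjusted p = 0.0016, lost at adjusted p = 0.128 with an estimated correlation) and not with siYAP1 (camera adjusted p = 0.123). Of the 22 fixed YAP and TAZ target genes only CCN1 fell, NT5E (0.55), AXL (-0.35) and ANKRD1 did not pass, and adjusted over the list alone 2 fell and 1 rose. The list as a whole did not pass (median 0.02, mean -0.04, adjusted p = 0.428). The calls of DDB2, AJUBA, MCM2, KIF23 and E2F1 were lost in 15, 12, 8, 2 and 1 of the 19 fits that left out 1 array, and that of AJUBA also with an intensity trend (0.0515).

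In all, 443 genes passed for the mean of both YAP siRNAs, 189 higher and 254 lower, and 69 passed in the same direction with each siRNA, 50 higher and 19 lower. A further 8 passed with each siRNA in opposite directions. With siYAP1 alone 225 genes passed and with siYAP2 alone 952. The count of 225 became 126, 136 or 130 without control replicate 1, 2 or 3, 149 without siYAP1 replicate 3 and 632 without the array labelled siTAZ2 replicate 3. The count of 952 became 612 without control replicate 3, 628 without siYAP2 replicate 3 and 1810 without the array labelled siTAZ2 replicate 3. With only control and YAP arrays in the fit the count of 443 became 860. With only control and siYAP2 arrays in the fit, that of siYAP2 alone became 1866. With array weights siYAP1 alone had 556 and siYAP2 alone 2374. Leaving out arrays, the count of 443 became 250, 248 or 240 without control replicate 1, 2 or 3 and 1144 without the array labelled siTAZ2 replicate 3, which enters this comparison only through the pooled spread. The count of 69 became 38, 40 or 32 without control replicate 1, 2 or 3, 45 or 41 without siYAP1 replicate 1 or 3, and 216 without the array labelled siTAZ2 replicate 3.

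TAZ knockdown was compared with control in the same way. After WWTR1 itself, ANKRD1, a cardiac ankyrin repeat gene widely used as a YAP and TAZ target, fell most, by 1.94 (SE 0.15, 3.84-fold, adjusted p = 7.21e-06). GSR, which encodes glutathione reductase, fell by 1.08, OSTM1 by 1.04, ZNF114 by 0.98, the glycerol-3-phosphate acyltransferase GPAT3 by 0.86, the autophagy gene ATG16L1 by 0.75, the histone methyltransferase KMT5A by 0.74 and CCN1 by 0.70 (adjusted p = 0.00335). BHMT, a liver enzyme that remethylates homocysteine, rose most, by 1.22 (SE 0.098, 2.34-fold), followed by CFDP1 (1.15), VPS4B (1.06), the ecto-nucleotidase NT5E (1.01), ZNF678 (1.00), the organic anion transporter SLC22A7 (0.99), DSC2 (0.98) and the tubulin gene TUBB1 (0.98). Of these, CFDP1, VPS4B, ZNF678 and DSC2 were higher than control in all 6 siRNA groups. CCN2 changed by -0.20 (adjusted p = 0.854) and AMOTL2 by -0.17 (adjusted p = 0.571), neither of which passed. Without the array labelled siTAZ2 replicate 3, CCN2 fell by 0.42 (adjusted p = 0.01). That mean joins opposite directions. CCN2 read 7.58 and 7.69 on the remaining siTAZ2 arrays, 8.68 to 8.82 in control, and 9.06 and 8.97 with siTAZ3, which did not lower it. YAP1 fell by 0.32 (adjusted p = 0.0367), a call that was lost in 9 of the 19 fits that left out 1 array, with adjusted p up to 0.172 without control replicate 1, and with an intensity trend (0.066). It passed with siTAZ3 (adjusted p = 0.0469) and not with siTAZ2 (0.191). With only control and TAZ arrays in the fit, the calls of GSR (adjusted p = 0.118), NT5E (0.0741), ZNF678 (0.0811), TUBB1 (0.069), CCN1 (0.0699) and YAP1 (0.179) were lost.

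Among the 22 YAP and TAZ target genes 4 fell after TAZ knockdown, namely ANKRD1, CCN1, MYOF by 0.58 and the receptor tyrosine kinase AXL by 0.52, while NT5E rose. The counts were the same adjusted over the list alone, 4 lower and 1 higher (median -0.15, adjusted p = 0.00373, and adjusted p = 0.0407 with an estimated correlation). The list was called with siTAZ2 (median -0.18, adjusted p = 0.000528, and adjusted p = 0.0259 with an estimated correlation) and not with siTAZ3 (median -0.03, adjusted p = 0.12), and AXL passed only with siTAZ2. Of 23 cytoskeleton and adhesion genes 5 fell, the annexin ANXA3 by 0.73, the integrin ITGAV by 0.72, the vinculin gene VCL by 0.50, CALD1 by 0.42 and ZYX by 0.40, and THBS1 rose by 0.30. ANXA3 and VCL passed with each TAZ siRNA, CALD1 only with siTAZ3, and ITGAV, ZYX and THBS1 only with siTAZ2. THBS1 rose almost equally, by 0.31 with siTAZ2 and 0.29 with siTAZ3. Adjusted over the list alone 6 fell and 1 rose (median -0.14, adjusted p = 2.3e-05, and adjusted p = 0.0055 with an estimated correlation). Of 21 hypoxia and glycolysis genes NDRG1 fell by 0.56, passing only with siTAZ2, and 2 fell adjusted over the list alone (median -0.11, adjusted p = 0.00229, and adjusted p = 0.0277 with an estimated correlation). SLC2A1 (-0.27), PFKFB3 (-0.25) and PFKP (-0.25) did not pass. Of 26 plasma protein genes 4 rose and 0 fell, the fibrinogen chains FGB (0.41), FGG (0.37) and FGA (0.32) and, only with siTAZ2, SERPINC1 (0.38), while PLG (0.40) did not pass, and 5 rose adjusted over the list alone (median 0.08, adjusted p = 3.94e-06, lost at adjusted p = 0.0706 with an estimated correlation). With only control and TAZ arrays in the fit, the calls of FGB (adjusted p = 0.102), FGG (0.0963), SERPINC1 (0.104), CALD1 (0.101), ITGAV (0.323), VCL (0.18), NDRG1 (0.121), CDC25C (0.169) and EHHADH (0.087) were lost. Of 26 mitosis genes CDC25C rose by 0.32. It passed with siTAZ2 (0.31) and not with siTAZ3, where it rose as much (0.33, limma adjusted p = 0.0654). Adjusted over the mitosis list alone 3 rose and 1 fell (median 0.13, camera adjusted p = 0.014, lost at adjusted p = 0.292 with an estimated correlation). NDC80 (0.48), BUB1 (-0.32) and CCNB1 (0.32) did not pass. Of 16 NF-kB and chemokine genes 0 passed, over all genes or adjusted over the list alone (limma, median -0.09, camera adjusted p = 0.0181, lost at adjusted p = 0.0693 with an estimated correlation and at 0.089 without control replicate 3). The largest changes there were ICAM1 (-0.60), RELB (-0.35), IL32 (-0.30) and NFKB2 (-0.25). Fatty acid oxidation genes (2 of 17 rose, 4 adjusted over the list alone, adjusted p = 0.0336) and hepatocyte transcription factors (0 of 13 over all genes, 1 rose adjusted over the list alone, adjusted p = 0.0416) were called higher as lists. EHHADH rose by 0.31, passing only with siTAZ3, and ACAA2 by 0.21, passing with neither siRNA alone, while CPT2 (0.34), CREB3L3 (0.29), CPT1A (0.25), FOXA1 (0.35), PROX1 (0.28), CEBPA (0.22) and ONECUT1 (0.22) did not pass. The value of CREB3L3 includes the array labelled siTAZ2 replicate 3, on which it read 7.39, against 9.73 and 9.53 on the other siTAZ2 arrays. Both list calls were lost with an estimated correlation (adjusted p = 0.0933 and adjusted p = 0.153). The first was also lost without control replicate 1 (0.0877), siTAZ2 replicate 1 (0.0598) or siTAZ3 replicate 1 (0.0688). It was lost as well without the dimmest 30% of genes (0.0654) and with array weights (0.065). The second was lost without the dimmest 30% of genes (0.0757) and without control replicate 1 (0.0518), 2 (0.0578) or 3 (0.063), siTAZ2 replicate 1 (0.0953) or 2 (0.0916), siTAZ3 replicate 1 (0.0804), siTAZ3_siYAP2 replicate 1 (0.0595) or siTAZ2_siYAP1 replicate 3 (0.0516). Per siRNA, mitosis genes (adjusted p = 0.00184) and fatty acid oxidation genes (0.0403) were called with siTAZ2 and not with siTAZ3 (0.226 and 0.0918). NF-kB and chemokine genes (0.0251) and hepatocyte transcription factors (0.0175) were called with siTAZ3 and not with siTAZ2 (0.0691 and 0.228), and all 4 of these calls were lost with an estimated correlation (adjusted p = 0.166, adjusted p = 0.113, adjusted p = 0.0914 and adjusted p = 0.11). The list tests with siTAZ2 include the array labelled siTAZ2 replicate 3 and were not repeated without it, and siTAZ3 has 2 arrays. These list calls therefore do not show that the TAZ siRNAs differ. The calls of ITGAV, VCL, NDRG1, SERPINC1, CDC25C and EHHADH were lost in 5, 3, 3, 5, 3 and 4 of the 19 fits that left out 1 array, and that of CDC25C also with an intensity trend (0.0503).

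For TAZ knockdown 503 genes passed, 288 higher and 215 lower, and 116 passed in the same direction with each siRNA, 74 higher and 42 lower. With only control and TAZ arrays in the fit 62 genes passed. In separate fits of control with 1 TAZ siRNA group, siTAZ2 gave 2 genes and siTAZ3 499, and 1 passed in both. The count of 503 became 207, 249 or 224 without control replicate 1, 2 or 3, 311 or 248 without siTAZ3 replicate 1 or 2, and 1199 without the array labelled siTAZ2 replicate 3. The count of 116 became 49, 62 or 71 without control replicate 1, 2 or 3, 57 or 40 without siTAZ3 replicate 1 or 2, and 278 without the array labelled siTAZ2 replicate 3, and 105 of the 116 were among these 278.

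Combined knockdown was compared with control in the same way. ANKRD1 fell by at least 3.86 (SE 0.15, adjusted p = 7.24e-10), to 5.04 and 4.88 in the combined groups, near the array median of 4.83 and not shown to be above background. CCN1 fell by 1.62 (SE 0.11, adjusted p = 1.08e-06), and CCN2, a secreted matricellular protein gene, by 1.41 (SE 0.22, adjusted p = 0.00179). AMOTL2 fell by 0.63 (SE 0.097, adjusted p = 0.00172). CCN2 fell by 1.98 with siTAZ2_siYAP1, while its change of -0.84 with siTAZ3_siYAP2 did not pass (adjusted p = 0.158). EPAS1, which encodes the hypoxia-inducible factor HIF-2alpha, fell by 1.72 (SE 0.24), ANXA3 by 1.40, FAM91A1 by 1.38 and RCBTB1 by 1.22. The largest rises were in DKK4 (1.55, SE 0.14), BHMT (1.43), SYT11 (1.29), RNASE2 (1.19), CFDP1 (1.08), BEX1 (1.07), the cytochrome P450 gene CYP4F11 (1.04) and VPS4B (1.04). Of these, DKK4, CFDP1 and VPS4B were higher than control in all 6 siRNA groups.

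Of the 22 YAP and TAZ target genes 7 fell after combined knockdown, with MYOF lower by 1.02, AXL by 1.01 and, only with siTAZ2_siYAP1, LATS2 by 0.32 beside those named, and NT5E rose by 0.90. Adjusted over the list alone 11 fell and 2 rose (median -0.31, adjusted p = 8.95e-10, and adjusted p = 0.00112 with an estimated correlation). Of 25 Hippo pathway and TEAD genes 5 fell, AJUBA (-0.84), WWC1 (-0.71), MOB1A (-0.28), AMOTL2 and LATS2, while TEAD2 (-0.53) did not pass, and 9 fell adjusted over the list alone (adjusted p = 3.26e-07, and adjusted p = 0.0277 with an estimated correlation). WWC1 passed only with siTAZ3_siYAP2 (adjusted p = 0.0771 with siTAZ2_siYAP1) and MOB1A only with siTAZ2_siYAP1 (0.979 with siTAZ3_siYAP2). AMOTL2 and LATS2 belong to both lists. Of 23 cytoskeleton and adhesion genes 3 fell, ANXA3, ITGAV by 0.70 and VCL by 0.40, and 5 fell adjusted over the list alone (adjusted p = 8.24e-07, and adjusted p = 0.00273 with an estimated correlation). ITGAV passed only with siTAZ2_siYAP1 (-1.05, adjusted p = 0.584 with the other pair) and VCL with neither pair alone, and TAGLN (-0.54) and ITGA2 (-0.41) did not pass. Of 17 fatty acid oxidation genes 2 rose, EHHADH by 0.28 and ACAA2 by 0.21, and 7 rose adjusted over the list alone (median 0.14, adjusted p = 0.00103, and adjusted p = 0.0233 with an estimated correlation). EHHADH rose by 0.30 with siTAZ2_siYAP1 and by 0.25 with siTAZ3_siYAP2, and ACAA2 by 0.235 and 0.18. EHHADH and ACAA2 passed only with siTAZ2_siYAP1. CREB3L3 (0.94), CYP4A11 (0.49) and CPT2 (0.27) did not pass. CREB3L3 read 7.39 on the array labelled siTAZ2 replicate 3, against at least 8.5 on all other arrays. That array enters this comparison only through the pooled spread, which it widens for CREB3L3. Of 20 bile acid and drug metabolism genes SULT2A1, a bile acid sulfotransferase, rose by 0.53, the only 1 also adjusted over the list alone (median 0.11, adjusted p = 0.00265, and adjusted p = 0.0297 with an estimated correlation). The last list was called with siTAZ3_siYAP2 (adjusted p = 0.00292, and adjusted p = 0.0402 with an estimated correlation) and not with siTAZ2_siYAP1 (adjusted p = 0.0582), and CYP1A1 (0.47), SLC51B (0.34) and CYP3A5 (0.27) did not pass. The calls of ITGAV and EHHADH were lost in 7 and 6 of the 19 fits that left out 1 array, and that of EHHADH also with an intensity trend (0.066).

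Further lists were called after combined knockdown only with the preset correlation. Of 29 replication genes 4 fell, GINS1 by 0.65 and, only with siTAZ3_siYAP2, E2F1 by 0.52, SLBP by 0.37 and RRM2 by 0.24, and adjusted over the list alone 5 fell and 1 rose (adjusted p = 0.00014, lost at adjusted p = 0.153 with an estimated correlation). CDC25A (-0.70) and CCNE2 (-0.39) did not pass. Of 26 plasma protein genes 3 rose, SERPINC1 by 0.60, FGB by 0.34 and, only with siTAZ2_siYAP1, FGG by 0.26, while APOC3 (0.45) and HP (0.31) did not pass, and 3 adjusted over the list alone (adjusted p = 0.000217, lost at adjusted p = 0.153 with an estimated correlation). Of 15 fatty acid synthesis genes 3 rose, ELOVL6 by 0.64, FADS2 by 0.55 and, only with siTAZ2_siYAP1, FADS1 by 0.45, while GPAM (0.36) did not pass, and 4 adjusted over the list alone (adjusted p = 0.00178, lost at adjusted p = 0.206 with an estimated correlation and at 0.0595 without siTAZ3_siYAP2 replicate 1). FADS1 rose almost equally, by 0.47 with siTAZ2_siYAP1 and 0.43 with siTAZ3_siYAP2 (limma adjusted p = 0.117). The fatty acid synthesis list was called with siTAZ2_siYAP1 (median 0.17, adjusted p = 5.99e-06, lost at adjusted p = 0.084 with an estimated correlation) and not with siTAZ3_siYAP2 (median 0.00, adjusted p = 0.271). Of 20 p53 target genes 3 rose, DDB2 by 0.48, only with siTAZ2_siYAP1, TP53I3 by 0.46, only with siTAZ3_siYAP2, and SPATA18 by 0.38, while SESN1 (0.38) did not pass, and 4 adjusted over the list alone (adjusted p = 0.012, lost at adjusted p = 0.344 with an estimated correlation). Cholesterol synthesis genes (2 of 18 rose, 2 adjusted over the list alone, adjusted p = 0.0148) and interferon-stimulated genes (1 of 24 rose, 2 adjusted over the list alone, adjusted p = 0.0181) were called higher. Hypoxia and glycolysis genes were called lower (0 of 21 passed in limma over all genes and 1 fell adjusted over the list alone, adjusted p = 0.0241). With an estimated correlation these 3 lists had adjusted p = 0.162, adjusted p = 0.0599 and adjusted p = 0.0706, and without control replicate 1 they had adjusted p = 0.0912, 0.0531 and 0.0711. Without siTAZ3_siYAP2 replicate 1 they had 0.169, 0.0979 and 0.0595, and hypoxia and glycolysis genes had 0.0646 without siTAZ2_siYAP1 replicate 3 and 0.0842 without the dimmest 30% of genes. Cholesterol synthesis genes were called with siTAZ2_siYAP1 (median 0.28, adjusted p = 2.16e-06, and adjusted p = 0.0259 with an estimated correlation) and not with siTAZ3_siYAP2 (median 0.03, adjusted p = 0.882). Hypoxia and glycolysis genes were called with siTAZ2_siYAP1 (adjusted p = 0.0157) and not with siTAZ3_siYAP2 (0.158), and interferon-stimulated genes with siTAZ3_siYAP2 (0.0197) and not with siTAZ2_siYAP1 (0.106). The last 2 calls were lost with an estimated correlation (adjusted p = 0.066 and adjusted p = 0.0701). In these lists SC5D rose by 0.50 and HMGCS1 by 0.45, only with siTAZ2_siYAP1, and XAF1 by 0.40, only with siTAZ3_siYAP2. TM7SF2 (0.31), CYP51A1 (0.27), RIGI (0.26), PARP9 (0.25), IFI6 (0.25), PFKP (-0.46), NDRG1 (-0.42), PFKFB3 (-0.39) and ALDOC (0.20) did not pass. The calls of DDB2, HMGCS1, FADS1, E2F1, XAF1 and FGB were lost in 14, 10, 8, 3, 3 and 1 of the 19 fits that left out 1 array.

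Combined knockdown changed 662 genes, 331 higher and 331 lower, and 193 in the same direction with each pair of siRNAs, 116 higher and 77 lower. A further 6 passed with each pair in opposite directions. With only control and combined arrays in the fit the count of 662 became 1145. It became 368, 396 or 357 without control replicate 1, 2 or 3 and 1578 without the array labelled siTAZ2 replicate 3. The count of 193 became 112, 125 or 126 without control replicate 1, 2 or 3, 103 without siTAZ3_siYAP2 replicate 2, and 486 without the array labelled siTAZ2 replicate 3, among which were all 193.

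**Figure D2:**
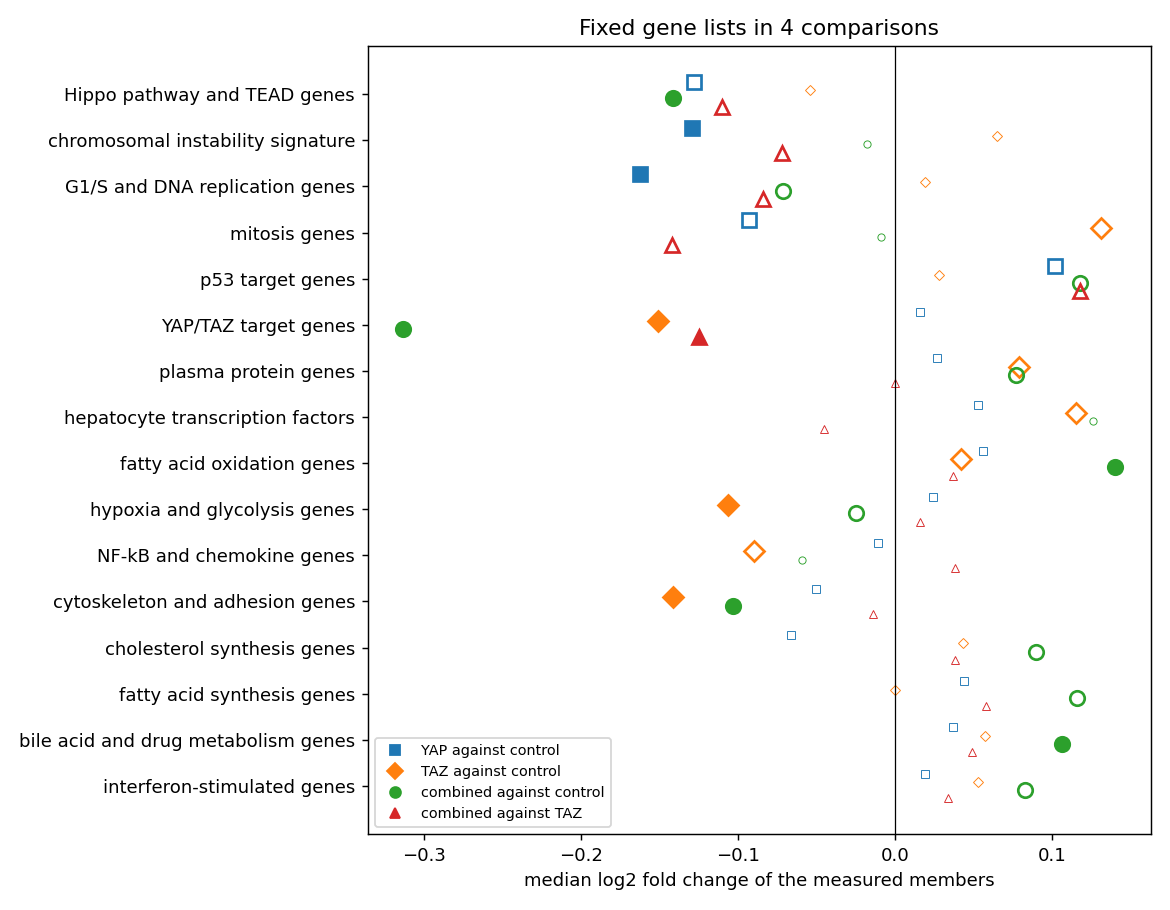
Median log2 fold change (horizontal axis) of the measured members of each fixed gene list called in at least 1 of the 4 comparisons (symbols); large symbols passed camera with the preset correlation, filled ones also with an estimated correlation, and small ones did not pass. The YAP and TAZ target list lay at -0.31 after combined knockdown, -0.15 after TAZ knockdown and 0.02 after YAP knockdown.

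Adding a YAP siRNA to a TAZ siRNA, a comparison within 1 deposit, lowered ANKRD1 by at least a further 1.92 (SE 0.13, adjusted p = 2.01e-06) and CCN1 by a further 0.93 (SE 0.097, adjusted p = 0.000225). The 7 genes that passed in the same direction with both pairs all fell: ANKRD1, YAP1 by 1.88, CCN1, CADM1 by 0.81, AJUBA by 0.63, the netrin gene NTN4 by 0.59 and HEG1 by 0.48. CCN2 fell by 1.21 (SE 0.19, adjusted p = 0.00688, and 0.0523 without siTAZ3_siYAP2 replicate 2), passing with siTAZ2_siYAP1 (adjusted p = 0.0397) and not with siTAZ3_siYAP2 (0.176). AMOTL2 fell by 0.45 (adjusted p = 0.0196, and up to 0.12 without siTAZ3 replicate 1, the call also being lost without siTAZ3_siYAP2 replicate 1 or 2), and passed with neither pair alone (0.397 and 0.0782). WWTR1 changed by 0.03 (adjusted p = 0.95), without passing. With only TAZ and combined arrays in the fit, the calls of AJUBA (adjusted p = 0.0682), NTN4 (0.0641), HEG1 (0.0844), CCN2 (0.218), AMOTL2 (0.245), AXL (0.234), PRIM1 (0.228), POLA1 (0.313), RAD51AP1 (0.249), ECT2 (0.329) and GDF15 (0.328) were lost. Of the 22 YAP and TAZ target genes 7 fell, with AXL by 0.48, only with siTAZ3_siYAP2, and MYOF by 0.44 and LATS2 by 0.31, neither of which passed with a single pair, beside those named, and 8 adjusted over the list alone (median -0.13, adjusted p = 5.14e-09, and adjusted p = 0.00123 with an estimated correlation). Of 25 Hippo pathway and TEAD genes AJUBA, AMOTL2 and LATS2 fell, while WWC1 (-0.32) and TEAD1 (-0.31) did not pass, and 7 fell adjusted over the list alone (adjusted p = 3.35e-05, lost at adjusted p = 0.055 with an estimated correlation). Of 26 mitosis genes ECT2 fell by 0.27, and 2 adjusted over the list alone (median -0.14, adjusted p = 1.26e-06, lost at adjusted p = 0.0535 with an estimated correlation). NDC80 (-0.34), KIF14 (-0.31) and ASPM (-0.27) did not pass. Of 29 replication genes 3 fell, the primase subunit PRIM1 by 0.51, POLA1 by 0.43 and, only with siTAZ3_siYAP2, RRM2 by 0.22, while CCNE2 (-0.44) and E2F1 (-0.33) did not pass, and 7 adjusted over the list alone (adjusted p = 2.28e-05, lost at adjusted p = 0.114 with an estimated correlation). In the chromosomal instability signature RAD51AP1 fell by 0.46, and 3 of 25 fell adjusted over the list alone (adjusted p = 0.000142, lost at adjusted p = 0.0502 with an estimated correlation), while MELK (-0.40), CCNB2 (-0.24) and TTK (-0.22) did not pass. Of 20 p53 target genes GDF15 rose by 0.43, the only 1 also adjusted over the list alone, while RRM2B (-0.35), TNFRSF10B (0.29) and CDKN1A (0.28) did not pass (adjusted p = 0.0241, lost at adjusted p = 0.37 with an estimated correlation and at 0.293 without the array labelled siTAZ2 replicate 3). The list call was also lost without siTAZ3 replicate 1 (0.0722), siTAZ3_siYAP2 replicate 1 (0.0595) or siTAZ2_siYAP1 replicate 3 (0.0953), and with array weights (0.28). The p53 list was called with siTAZ3_siYAP2 (adjusted p = 0.00862, lost at adjusted p = 0.331 with an estimated correlation) and not with siTAZ2_siYAP1 (0.419). The cholesterol synthesis list, not called for the mean, was higher with siTAZ2_siYAP1 (median 0.16, adjusted p = 5.92e-05, and adjusted p = 0.0446 with an estimated correlation) and lower with siTAZ3_siYAP2 (median -0.08, adjusted p = 0.0279, lost at adjusted p = 0.194 with an estimated correlation). PRIM1, POLA1, RAD51AP1, ECT2 and GDF15 passed with neither pair alone. The calls of ECT2, GDF15, POLA1, AXL, RAD51AP1 and PRIM1 were lost in 13, 8, 6, 4, 3 and 2 of the 19 fits that left out 1 array, and that of ECT2 also without the dimmest 30% of genes (0.0554).

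In this comparison 191 genes passed, 32 higher and 159 lower. The combined groups received 40 nM of siRNA in total and the TAZ groups 20 nM. With only TAZ and combined arrays in the fit 23 genes passed. In separate limma fits of each combined group with its TAZ group, 5 and 4 genes passed and 0 in both. There 1283 and 1787 had unadjusted p under 0.05. The count of 191 became 57 or 85 without siTAZ3 replicate 2 or 1, 75 without siTAZ3_siYAP2 replicate 2, 122 without siTAZ2_siYAP1 replicate 1, 289 without siTAZ2 replicate 1 and 331 without the array labelled siTAZ2 replicate 3. The count of 7 became 2 without siTAZ3 replicate 1 or 2, 4 without siTAZ3_siYAP2 replicate 1 or 2 or siTAZ2_siYAP1 replicate 2, and 16 without the array labelled siTAZ2 replicate 3, among which were all 7.

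Adding a TAZ siRNA to a YAP siRNA lowered ANKRD1 by at least 3.53 (SE 0.13), WWTR1 by 2.44, CCN2 by 1.26 (SE 0.18, adjusted p = 0.00132), EPAS1 by 1.26, C12orf75 by 1.14 and CCN1 by 0.92. BHMT (0.95), SYT11 (0.89), DKK4 (0.71), the chemokine decoy receptor ACKR2 (0.69) and YAP1 (0.52, adjusted p = 0.000281) rose. The ceramidase gene ASAH2 rose by 0.74 (adjusted p = 0.00741, and 0.0647 without siTAZ3_siYAP2 replicate 2). AMOTL2 fell by 0.37 (adjusted p = 0.0247), a call lost in 6 of the 19 fits that left out 1 array and with an intensity trend (0.054). CCN2, EPAS1, C12orf75 and ASAH2 passed with siTAZ2_siYAP1 (adjusted p up to 0.00669 for ASAH2) and not with siTAZ3_siYAP2 (0.28 for CCN2, 0.884 for EPAS1, 1.00 for C12orf75 and 0.491 for ASAH2). DKK4, ACKR2 and AMOTL2 passed with siTAZ3_siYAP2 and not with siTAZ2_siYAP1 (0.115, 0.155 and 0.556). Of the 22 YAP and TAZ target genes 8 fell, and adjusted over the list alone 9 fell and 1 rose (adjusted p = 2.04e-12, and adjusted p = 0.000652 with an estimated correlation). Cytoskeleton and adhesion genes fell as a list (3 of 23, and adjusted over the list alone 8 fell and 2 rose; adjusted p = 1.21e-05, and adjusted p = 0.00548 with an estimated correlation). Cholesterol synthesis genes rose as a list (2 of 18, and 7 adjusted over the list alone; adjusted p = 2.71e-06, and adjusted p = 0.0213 with an estimated correlation), as did fatty acid oxidation genes (2 of 17, and 2 adjusted over the list alone; adjusted p = 0.00782, and adjusted p = 0.0485 with an estimated correlation). Here 574 genes passed, 248 higher and 326 lower, against 277 without siTAZ3_siYAP2 replicate 2, 1612 without the array labelled siTAZ2 replicate 3 and 1131 with only YAP and combined arrays in the fit.

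Further lists were called in this comparison only with the preset correlation. Hippo pathway and TEAD genes were lower (3 of 25, and 5 adjusted over the list alone; adjusted p = 0.00425, and adjusted p = 0.162 with an estimated correlation). Plasma protein genes were higher (3 of 26, and 3 adjusted over the list alone; adjusted p = 0.000579, and adjusted p = 0.168 with an estimated correlation). The chromosomal instability signature was higher (1 of 25 rose and 1 fell, and 8 and 1 adjusted over the list alone; adjusted p = 0.000284, and adjusted p = 0.055 with an estimated correlation), as were replication genes (1 of 29 rose and 1 fell, and 3 and 1 adjusted over the list alone; adjusted p = 0.00305, and adjusted p = 0.254 with an estimated correlation). Fatty acid synthesis genes were higher (1 of 15, and 5 adjusted over the list alone; adjusted p = 0.0178, and adjusted p = 0.334 with an estimated correlation). Hypoxia and glycolysis genes were lower (1 of 21, and 3 adjusted over the list alone; adjusted p = 0.0452, and adjusted p = 0.105 with an estimated correlation). Hippo genes had 0.0529 without siYAP1 replicate 1 and replication genes 0.0689 without siTAZ3_siYAP2 replicate 1. Fatty acid synthesis genes had 0.0991 without siYAP1 replicate 1, 0.263 without siTAZ3_siYAP2 replicate 1 and 0.0913 without siTAZ2_siYAP1 replicate 3. Hypoxia genes had 0.124 without siYAP1 replicate 3, 0.08 without siYAP2 replicate 1, 0.0995 or 0.0668 without siTAZ3_siYAP2 replicate 1 or 2, 0.0601 without the array labelled siTAZ2 replicate 3, 0.115 without siTAZ2_siYAP1 replicate 3, 0.0524 with an intensity trend and 0.108 without the dimmest 30% of genes. Per pair, over 162 tests, cholesterol synthesis genes were called with siTAZ2_siYAP1 (adjusted p = 3.43e-05, and adjusted p = 0.0389 with an estimated correlation) and siTAZ3_siYAP2 (adjusted p = 0.0162, lost at adjusted p = 0.172 with an estimated correlation). Cytoskeleton and adhesion genes likewise had adjusted p = 0.0108 and adjusted p = 0.137 with an estimated correlation. Fatty acid oxidation genes were called with neither pair (0.0666 and 0.121). Plasma protein, fatty acid synthesis and hypoxia genes (0.423, 0.965 and 0.962) and Hippo genes (0.058) were not called with siTAZ3_siYAP2, nor replication genes (0.134) with siTAZ2_siYAP1.

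Set directly against TAZ knockdown, YAP knockdown left ANKRD1 higher by 1.61 (SE 0.13), EPAS1 by 0.98, ZNF114 by 0.98 and MAB21L3 by 1.03, and had lower PDCD4 (-1.47), LYRM1 (-1.39), LIN7C (-1.35) and the deoxycytidine kinase gene DCK (-1.34). Tested per YAP siRNA, LYRM1, LIN7C and DCK were lower with siYAP2 (-2.73, -2.76 and -2.34) and not with siYAP1 (-0.04, 0.07 and -0.35; adjusted p = 0.885, 0.718 and 0.292), so these means reflect siYAP2 alone. PDCD4 was lower with siYAP2 by far more (-2.51) than with siYAP1 (-0.43). EPAS1 passed with siYAP1 (1.41) and not with siYAP2 (0.55, adjusted p = 0.284). WWTR1 was higher by 2.47 and YAP1 lower (-2.40). CCN1 differed by -0.01 (adjusted p = 0.986), CCN2 by 0.05 (adjusted p = 0.954) and AMOTL2 by -0.09 (adjusted p = 0.741), none of which passed. Without the array labelled siTAZ2 replicate 3, CCN2 was higher by 0.27 (adjusted p = 0.0285). The direction held against siTAZ2 only. CCN2 read 8.43 to 8.88 with the YAP siRNAs, 7.58 and 7.69 on the remaining siTAZ2 arrays, and 9.06 and 8.97 with siTAZ3. With only YAP and TAZ arrays in the fit, the call of EPAS1 was lost (adjusted p = 0.0706). With YAP siRNAs 11 of 29 replication genes were lower and 1 higher (15 and 2 adjusted over the list alone; adjusted p = 1.03e-08, and adjusted p = 0.0425 with an estimated correlation). Of 26 mitosis genes 6 were lower (8 lower and 1 higher adjusted over the list alone; adjusted p = 2.98e-07, and adjusted p = 0.0436 with an estimated correlation), and of the 25 genes of the chromosomal instability signature 10 were lower and 1 higher (17 and 2 adjusted over the list alone; adjusted p = 1.48e-09, and adjusted p = 0.0055 with an estimated correlation). Of 23 cytoskeleton and adhesion genes 6 were higher and 1 lower (10 and 2 adjusted over the list alone; adjusted p = 0.00551, and adjusted p = 0.0407 with an estimated correlation). Plasma protein genes (5 of 26 lower, 7 adjusted over the list alone, adjusted p = 0.000319, and adjusted p = 0.162 with an estimated correlation) and cholesterol synthesis genes (3 of 18 lower, 6 adjusted over the list alone, adjusted p = 0.00134, and adjusted p = 0.0706 with an estimated correlation) were called lower. Hypoxia and glycolysis genes (3 of 21 higher, 3 adjusted over the list alone, adjusted p = 0.0141, and adjusted p = 0.055 with an estimated correlation) were called higher. So were p53 target genes (5 of 20 higher and 1 lower, 6 and 1 adjusted over the list alone, adjusted p = 0.0178, and adjusted p = 0.344 with an estimated correlation), a call lost at 0.179 without the array labelled siTAZ2 replicate 3 and at 0.0906 with array weights. Per YAP siRNA, plasma protein (adjusted p = 0.246), hypoxia (0.423) and cytoskeleton genes (0.0761) were not called with siYAP2, nor cholesterol synthesis (0.253) and p53 target genes (0.48) with siYAP1. In total 1429 genes differed, 626 higher and 803 lower, against 843 without siTAZ3 replicate 2, 2371 without the array labelled siTAZ2 replicate 3 and 822 with only YAP and TAZ arrays in the fit.

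The effect of a YAP siRNA was then compared between cells with and without a TAZ siRNA, a difference in which an additive gap between the deposits cancels. A shift confined to the control arrays and an effect of the total siRNA dose do not cancel in it. Of the 32 genes that passed, 16 were higher than control in all 6 siRNA groups. ANKRD1 responded more strongly with a TAZ siRNA present, by -1.59 (SE 0.20, adjusted p = 0.002). YAP1 itself fell less there, by 0.84 (SE 0.098, adjusted p = 0.00105). VPS4B (-1.07), CFDP1 (-1.06) and DSC2 (-1.04) also differed, having risen with a YAP siRNA alone and not passed on top of a TAZ siRNA. Tested per pair, YAP1 and DSC2 passed with both, and ANKRD1, VPS4B and CFDP1 with siYAP1 and siTAZ2 but not with siYAP2 and siTAZ3 (ANKRD1 -1.24, adjusted p = 0.154; VPS4B 0.0729; CFDP1 0.154). ZNF678 (-1.29, adjusted p = 0.0245), TMED5 (0.45, adjusted p = 0.024) and WT1 (0.52, adjusted p = 0.0346) passed, but their calls were lost in 8, 8 and 14 of the 19 fits that left out 1 array, and that of WT1 also with an intensity trend (0.22). The differences for WWTR1 (0.38), CCN1 (-0.22), CCN2 (-1.06, adjusted p = 0.318) and AMOTL2 (-0.19) did not pass, and CCN2 had adjusted p = 0.00266 without the array labelled siTAZ2 replicate 3. The YAP and TAZ target list fell more with a TAZ siRNA present (1 of 22 passed, 4 adjusted over the list alone, median -0.15, adjusted p = 5.47e-06, and adjusted p = 0.00548 with an estimated correlation). Replication genes were called in the opposite direction (0 of 29 passed in limma, over all genes or adjusted over the list alone; median 0.08, adjusted p = 0.014, lost at adjusted p = 0.334 with an estimated correlation). That call was also lost without control replicate 2 (0.0555), siYAP1 replicate 1 (0.0529), siTAZ2 replicate 1 (0.0804), siTAZ3 replicate 1 (0.0924) or siTAZ3_siYAP2 replicate 1 (0.1). The interaction passed in 32 genes, 4 higher and 28 lower. This count became 17, 17 or 20 without control replicate 1, 2 or 3, 16, 21 or 18 without siYAP2 replicate 1, 2 or 3, 19 without siYAP1 replicate 2, 20 or 17 without siTAZ3 replicate 1 or 2, 16 without siTAZ2_siYAP1 replicate 2, 20 without siTAZ3_siYAP2 replicate 2 and 100 without the array labelled siTAZ2 replicate 3.

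The independent siRNAs against 1 gene were also set against each other. LIN7C was 7.12-fold higher with siYAP1 than with siYAP2 (2.83 on the log2 scale, SE 0.067), LYRM1 6.43-fold, the microtubule-severing gene SPAST 5.39-fold, CARNMT1 5.34-fold and TNFRSF21 4.89-fold, while ZCRB1 (-2.04), MIS18A (-1.98), the catalase gene CAT (-1.81), PEX19 (-1.40) and BEX1 (-1.39) were lower. YAP1 differed by -0.02 (95% interval -0.20 to 0.16, adjusted p = 0.963). WWTR1 (-0.06), CCN1 (0.02), CCN2 (-0.27) and AMOTL2 (-0.09) did not pass, and ANKRD1 was higher with siYAP1 by 0.69 (adjusted p = 0.0239, and up to 0.12 without siYAP2 replicate 2, the call also being lost without siYAP2 replicate 3 or siYAP1 replicate 1 or 2). In total 1236 genes differed, 746 higher and 490 lower, against 812 without siYAP2 replicate 2 and 2171 without the array labelled siTAZ2 replicate 3.

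**Figure D3:**
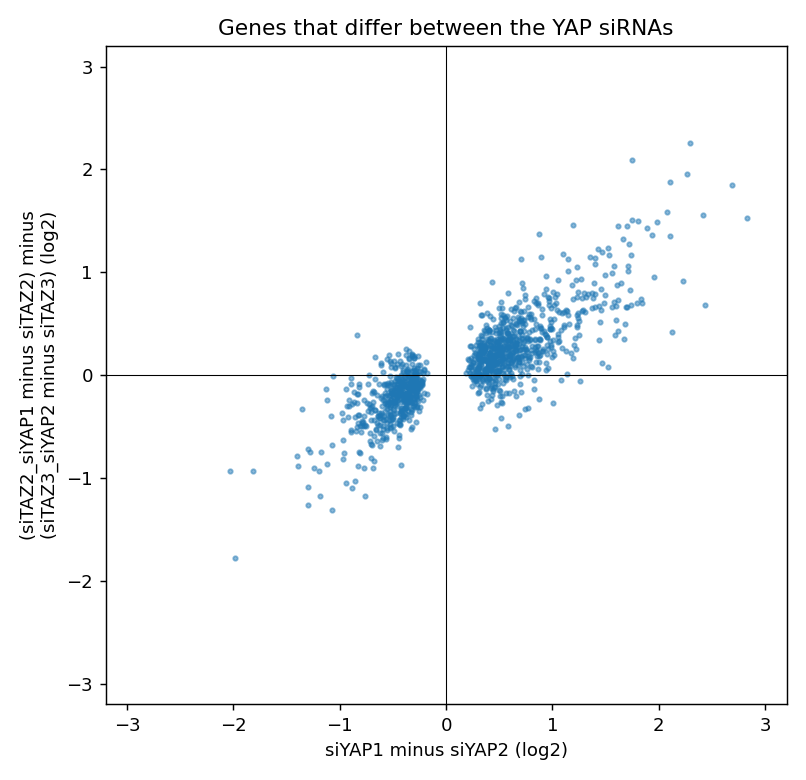
Each point is 1 of the 1236 genes that differ between siYAP1 and siYAP2: the log2 difference between the YAP siRNAs used alone (horizontal axis) and the same difference when each was added to its TAZ siRNA, on other arrays (vertical axis). Across these genes r was 0.835 and the slope 0.515.

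Between siTAZ2 and siTAZ3, the metallothionein gene MT1X (-1.29) and the immediate early gene IER3 (-1.12) were lower with siTAZ2, and these 2 calls held whichever array was left out. With only the TAZ arrays in the fit they were lost (MT1X and IER3 both at adjusted p = 0.578), as 0 genes passed there in limma and 1226 had unadjusted p under 0.05. DIPK2A (1.20), SCML1 (1.10), CDC37L1 (1.08), ZNF468 (1.03) and TMED6 (0.96) were higher and TNS4 (-1.42), MT1F (-1.38) and EGR1 (-1.25) lower, all calls that were lost without siTAZ3 replicate 1. The highest adjusted p on leaving out 1 array was 0.0562 for CDC37L1, 0.0714 for SCML1, 0.116 for TMED6, 0.0827 for DIPK2A, 0.213 for ZNF468, 0.195 for MT1F, 0.337 for EGR1 and 0.336 for TNS4. The last call was lost in 17 of the 19 fits. WWTR1 (0.50, adjusted p = 0.0713), YAP1 (0.17), CCN1 (-0.07), ANKRD1 (0.17) and AMOTL2 (0.06) did not pass, and WWTR1 had adjusted p = 0.00502 without the array labelled siTAZ2 replicate 3. CCN2 differed by -0.95 (adjusted p = 0.163), and by -1.39 (adjusted p = 2.88e-06) without the array labelled siTAZ2 replicate 3, on which it read 8.94 against 7.58 and 7.69 on the other siTAZ2 arrays. In total 208 genes differed, 111 higher and 97 lower. This count became 20 or 39 without siTAZ3 replicate 1 or 2, 94 without siTAZ2 replicate 2 and 1104 without the array labelled siTAZ2 replicate 3.

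Each siRNA was compared with the same control arrays, which alone correlates the results. Across genes, which are not independent replicates, the log2 fold changes of siYAP1 and siYAP2 had r = 0.249, where simulated groups without any effect gave 0.5, and their covariance was 0.00742 against 0.0083 simulated. For siTAZ2 and siTAZ3 r was 0.538 against 0.447 and the covariance 0.0169 against 0.00827. For the 2 combined groups r was 0.449 against 0.448 and the covariance 0.0166 against 0.00832. The simulation gave all arrays the spread pooled over the 7 groups, to which the array labelled siTAZ2 replicate 3 adds. The SD of deviations from the group mean was 0.251 on that array and 0.098, 0.093 and 0.097 on the control arrays. The simulated values may therefore be too high, and the YAP siRNAs are not shown to share less than control noise alone would give. At the unadjusted p-values reached here, the simulated groups shared at most 7, 5 and 7 genes in 100 runs for the YAP, TAZ and combined pairs. Independent lists of these sizes would share 1.55 higher and 2.71 lower genes for the YAP siRNAs, 1.74 and 1.72 for the TAZ siRNAs, and 3.13 and 5.3 for the combinations. With 3 control arrays the controls could not be split into parts of at least 2, so part of the excess may come from the shared controls.

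Markers of other cell types did not pass as lists in any of the 7 comparisons tested: the lowest adjusted p was 0.472 for fibroblast and stellate cell markers, 0.234 for endothelial and 0.212 for blood cell markers. ACTA2, a smooth muscle actin on the first of these lists, rose by 0.47 after combined knockdown (adjusted p = 0.00998, and 0.0836 without control replicate 3), and passed only with siTAZ3_siYAP2 (0.203 with siTAZ2_siYAP1). It also rose by 0.39 after TAZ knockdown (adjusted p = 0.0419), a call lost in 13 of the 19 fits that left out 1 array, with an intensity trend (0.0686) and with only control and TAZ arrays in the fit (0.235), and it passed with neither TAZ siRNA alone. On adding a TAZ siRNA to a YAP siRNA it rose by 0.41 (adjusted p = 0.00898), and it was lower with YAP than with TAZ knockdown (-0.33, adjusted p = 0.0165) and with siYAP1 than with siYAP2 (-0.83, adjusted p = 8.39e-05). The lowest adjusted p was 0.0512 for ATF4 and unfolded protein response genes, 0.0615 for Wnt target genes, 0.0663 for cytosolic ribosomal protein genes and 0.0912 for TGF-beta and BMP response genes. It was 0.129 for amino acid transport and glutamine genes, 0.13 for growth factor and angiogenic ligand genes, 0.269 for Notch pathway genes and 0.269 for fetal liver and biliary markers. Over all 189 list tests 51 passed with the preset correlation, and 20 of these also with an estimated correlation.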

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

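The tests of the 3 patterns below were chosen after the patterns had been seen. The counts over other splits of the arrays were planned. The following comparisons were singled out because the test of a difference between effects passed: 32 genes for the YAP siRNA effect with against without a TAZ siRNA, 1236 genes between siYAP1 and siYAP2, and 208 genes between siTAZ2 and siTAZ3. Among the genes of the first, ANKRD1 (-1.59), ZNF678 (-1.29), VPS4B (-1.07), CFDP1 (-1.06) and DSC2 (-1.04) were lower and YAP1 (0.84), WT1 (0.52) and TMED5 (0.45) higher.

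A group of 19 genes was higher than in control in all 6 siRNA groups, among them CFDP1, VPS4B, DSC2, DRAM1, ZNF678 and DKK4, and 16 of them passed the interaction test. Chance values of the shared control arrays stay open: simulated arrays without effect, taken at the unadjusted p-values reached here, gave at most 1 such gene in 100 runs, but their spread is assumed. The median rise was 0.618 with YAP siRNAs, within the control's deposit, and 0.728 with TAZ siRNAs, but the genes were chosen for both rises, so a gap between the deposits cannot be told apart in the TAZ and combined groups. The median ratio of the combined rise to the sum of both single rises was 0.501, and DKK4 did rise further on adding a YAP siRNA (0.61). The genes were chosen for being higher than the same control arrays. Low control values in them lower both this ratio and the interaction, so neither decides about additive effects of YAP and TAZ loss. A control siRNA or control cultures that differ from all other arrays remain possible, in line with a median change of -0.017 on adding a YAP siRNA to a TAZ siRNA, and an effect of YAP or TAZ loss that is already complete with either stays open.

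The 1236 genes that differ between siYAP1 and siYAP2 may follow the sequence of each siRNA. On arrays not used in that comparison, the same difference measured on top of the TAZ siRNAs correlated with it across these genes at r = 0.835 (Spearman 0.826), with 87.8% of the genes in the same direction. The slope of the second difference on the first was 0.515, so the second was smaller. The second difference includes the array labelled siTAZ2 replicate 3. A culture or array batch of 1 of the YAP groups is argued against by the same value of 0.835, since the second set of arrays lies in another deposit. Unequal lowering of the YAP1 mRNA is argued against by the YAP1 difference of -0.019 (95% interval -0.196 to 0.159). The arrays do not measure YAP protein, so unequal loss of the protein stays open. A dependence of the second measure on siTAZ2 and siTAZ3 stays open, because each TAZ siRNA was combined with only 1 YAP siRNA.

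The array labelled siTAZ2 replicate 3 may not hold siTAZ2. On 983 genes that separate the siTAZ2 from the siTAZ3 combination after allowance for the YAP siRNAs, it scored -0.098, where the other siTAZ2 arrays scored 0.715 and 0.665, the siTAZ3 arrays 0.018 and -0.018 and the controls 0.163 to 0.18. Cells without a TAZ siRNA are argued against by WWTR1, which differed by -2.778 from the control mean. The distance of this array from the siTAZ3 mean was 2.02 times that expected of a siTAZ3 array of ordinary quality. That expectation rests on the 2 siTAZ3 arrays alone. The SD of differences between 2 arrays of a group ranged from 0.162 to 0.249 over the groups, so this ratio alone does not decide. On the array labelled siTAZ2 replicate 3, 75 genes lay over 1 log2 unit outside the range of all other arrays, against at most 3 for each other array, and 671 genes differed more than 2-fold from the mean of the other siTAZ2 arrays. A siTAZ3 or further TAZ siRNA sample of poorer RNA or hybridisation quality stays open, and no biological explanation was tested.

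Other splits of the same arrays into groups of the same sizes tested whether the counts of genes can arise by chance. For combined knockdown against control 1 of 100 splits, the real one, gave as many as 662 genes (highest other 419). It was also 1 of 100 for combined against YAP knockdown (574, highest other 401) and YAP against TAZ knockdown (1429, highest other 596). For the interaction it was 1 of 100 (32, highest other 1). Other splits mix siRNA groups, so real differences between siRNAs enlarge their spread and lower their counts. Low counts in them therefore cannot exclude chance. In all of these but the interaction, the real split also separates the deposits, so a gap between deposits could give its count. For YAP knockdown 2 of 84 splits gave as many as 443 and the highest other gave 1056, and for genes shared by both YAP siRNAs 3 of 84 gave as many as 69 and the highest other gave 570. In both, that split set the siYAP2 arrays against control and siYAP1 arrays, a structure of the siRNA groups. For combined against TAZ knockdown 3 of 100 gave as many as 191, and the highest other, 1830, put siTAZ3 arrays and the array labelled siTAZ2 replicate 3 on 1 side and the other siTAZ2 arrays on the opposite side. For TAZ knockdown 5 of 100 gave as many as 503, so chance was not excluded, and the highest other, 909, again set that array with siTAZ3. With 3 arrays against 3 there are only 10 splits, too few for a share under 0.05: the real count and the highest other were 1236 and 0 for siYAP1 against siYAP2, 225 and 0 for siYAP1, 952 and 0 for siYAP2, 606 and 0 for siTAZ2 and 624 and 0 for siTAZ2_siYAP1 against control, and 56 and 1 for siTAZ2_siYAP1 against siTAZ2, each with 1 split as large, the real one. On leaving out 1 array, the count of 606 ranged from 273 to 1305, that of 624 from 314 to 1547 and that of 56 from 26 to 99. The upper ends came without the array labelled siTAZ2 replicate 3.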

How the results depend on the processing

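The alternatives were planned before the data were examined, except the block, the array weights and the left-out arrays for gene lists. All 21 counts of genes stayed within 1.5 times of their value with the intensity trend, without the dimmest 30% of genes, with the mean of probe sets, with quantile normalization once more and with median centring. The last 3 could move almost nothing, since the arrays already shared 1 distribution and nearly all genes had 1 probe set. With only the groups compared in the fit, counts became 860 for YAP knockdown, 62 for TAZ, 1145 for combined knockdown, 23 for combined against TAZ, 1131 for combined against YAP, 822 for YAP against TAZ, 0 for siTAZ2 against siTAZ3 (limma, 1226 genes at unadjusted p under 0.05), 1 for both TAZ siRNAs and 0 for both pairs of combined against TAZ (5 and 4 genes per pair, and 1283 and 1787 at unadjusted p under 0.05). Replicate numbers did not pair the samples: of 22 same-numbered pairs 4 had deviations correlated over 0.1 (range -0.28 to 0.23). With the replicate block the counts were 113 for TAZ, 295 for combined knockdown, 163 for combined against YAP, 520 for YAP against TAZ, 39 for both TAZ siRNAs and 90 for both combined pairs. With array weights they were 1303 for YAP, 1772 for TAZ, 1579 for combined knockdown, 376 for combined against TAZ, 1214 for combined against YAP, 2930 for YAP against TAZ, 121 for the interaction, 2140 between YAP siRNAs, 1553 between TAZ siRNAs, and 212, 434, 389 and 25 for both siRNAs or pairs of YAP, TAZ, combined, and combined against TAZ. Leaving out 1 array gave 240 to 1144 for YAP, 207 to 1199 for TAZ, 357 to 1578 for combined knockdown, 57 to 331 for combined against TAZ, 277 to 1612 for combined against YAP, 843 to 2371 for YAP against TAZ, 16 to 100 for the interaction, 812 to 2171 between YAP siRNAs and 20 to 1104 between TAZ siRNAs. For both siRNAs or pairs it gave 32 to 216, 40 to 278, 103 to 486 and 2 to 16. All upper ends came without the array labelled siTAZ2 replicate 3, and where an arm kept 1 array it was assumed to vary like the other groups. Signs turned only for small values that had not passed: with the block CCN1 in YAP against TAZ (0.082), with array weights WWTR1 in combined against TAZ (-0.023), YAP1 between YAP siRNAs (0.006), and CCN1 (0.107) and ANKRD1 (-0.072) between TAZ siRNAs. Leaving out 1 array, the ranges were -0.055 to 0.052 for CCN1 and -0.07 to 0.272 for CCN2 in YAP against TAZ, -0.072 to 0.044 for YAP1 and -0.057 to 0.086 for CCN1 between YAP siRNAs, -0.097 to 0.212 for AMOTL2, -0.198 to 0.016 for CCN1 and -0.092 to 0.298 for ANKRD1 between TAZ siRNAs, and -0.046 to 0.1 for WWTR1 in combined against TAZ. Of the calls of named genes 57 were not kept with only the groups compared in the fit, 43 with the block, 9 with the trend and 4 without the dimmest genes. Of the list calls 7 were not kept with the block, 3 with array weights, 1 with the trend and 4 without the dimmest genes. Of 190 calls of named genes 126 held whichever array was left out, as did 37 of 51 list calls. Of the list calls 20 held with an estimated correlation and 42 with fry. Where the array labelled siTAZ2 replicate 3 is in no compared group, leaving it out can act only through the pooled spread. The cause of the other changes was not tested.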

Other observations

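The tests per siRNA and the correlations across genes in this part were chosen after the data were seen. The list test of the difference was planned, and the hypothesis was written after its result. The replication gene list was called lower with each YAP siRNA, though 0 of its 29 genes passed in limma with siYAP1 and 6 fell with siYAP2. The median was -0.17 with siYAP1 (camera over 216 tests, adjusted p = 1.03e-07) and -0.16 with siYAP2 (adjusted p = 1.6e-08), and with an estimated correlation adjusted p = 0.0577, which ends the siYAP1 call, and adjusted p = 0.0446. On top of a TAZ siRNA the list was lower with siYAP1 by a median of -0.07 (adjusted p = 0.0197) and with siYAP2 by -0.08 (adjusted p = 5.92e-05), on arrays not shared with the former, but with an estimated correlation these had adjusted p = 0.351 and adjusted p = 0.129. The YAP and TAZ target list did not pass with siYAP1 alone (adjusted p = 0.897) or siYAP2 alone (adjusted p = 0.257). It passed when either was added to a TAZ siRNA, at adjusted p = 2.43e-07 and 5.49e-06, and with an estimated correlation at adjusted p = 0.00355 and adjusted p = 0.00727.

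A hypothesis from these values is that YAP and TAZ may stand in for each other at part of their target genes, so that a YAP siRNA lowers them more once TAZ is depleted. The observation that led to it, and so not an independent test of it, is the difference of the effects over the 22 fixed target genes, with an unadjusted camera p of 4.05e-07 and a median of -0.15, and ANKRD1 (-1.59) was the only member past the threshold over all genes. The test uses the control arrays, which may differ from the rest for the 19 genes described above, and YAP1 itself fell less in the combined groups.

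Across genes, the effect of siYAP2 alone and its effect on top of siTAZ3 share no arrays and had r = 0.861 over the 951 genes called with siYAP2, leaving out YAP1. The matching value for siYAP1 and siTAZ2 was 0.709 over 224 genes. Over all genes these values were 0.505 for siYAP2 and 0.038 for siYAP1, so for siYAP1 the relation was seen only over the called genes. The values in this part that involve siTAZ2 include the array labelled siTAZ2 replicate 3 and were not computed without it. The lower siYAP1 values therefore cannot be read as a property of siYAP1. Crossing the siRNAs gave 0.086 for siYAP1 against siYAP2 on top of siTAZ3 and 0.117 for siYAP2 against siYAP1 on top of siTAZ2, and -0.031 and 0.097 over all genes. The effects of the YAP siRNAs on top of their TAZ siRNAs, siYAP1 against siYAP2, share no arrays either. They had r = 0.441 over the 55 genes called with siYAP1 on top of siTAZ2, with 74.5% in the same direction. The Spearman value there was lower, 0.223, and r over all genes was 0.249.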
